A study of Aspergillus nidulans with 12 samples.

How the data were processed

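The deposited files are the scanner output of 12 2-colour Agilent arrays with 43803 spots that are not controls. Per the labels, mycelium of strains R21 and ∆gprH was grown for 24 h in minimal medium with glucose, washed with water and moved to medium without carbon for 4 h or 8 h, with 3 biological repetitions of each point. Total RNA was extracted with a column kit and amplified to labelled cRNA, with Cy3 for glucose-grown and Cy5 for starved RNA on every array, per the channel labels. The labelling protocol speaks of untreated and SEB-treated samples, which matches nothing else in the labels, so the assignment rests on the channel labels. Across genes, 4 h and 8 h arrays of a strain correlated with r between 0.981 and 0.996 in Cy3 and between 0.924 and 0.969 in Cy5, which goes with Cy3 holding RNA from the same condition at both times. The images were read with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. Per the file headers, the intensity columns hold mean signals and local background medians of each spot in both channels, and processed signals after the program's background subtraction and dye normalization. Per the file headers, the program also gives a log10 ratio of processed Cy5 over Cy3 and marks for outlying, saturated and well-above-background spots. The deposited value table of the series holds log2 ratios: it differed from the log2 ratio of the processed signals by at most 1.39e-05 on any array, which settles its scale, direction and centring. Its column medians were −0.098, −0.032 and −0.096 for R21 at 4 h, −0.0996, −0.0522 and −0.0585 for R21 at 8 h, 0.0738, −0.0375 and −0.0108 for ∆gprH at 4 h and −0.142, −0.0732 and −0.0784 for ∆gprH at 8 h. The genome build behind the probes is not given in the sources used here, and no coordinates are printed.

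The array holds 1 probe for each of 11143 genes, with a median of 4 spots. Genes were named by the RefSeq table of assembly ASM1142v1, which gave a symbol for 774 genes on the array, 740 of them tested. Other genes carry the name given in a gene list or their locus name. For 131 genes the probe sequence equals that of another gene, and none of these is named here. Because each gene has a single probe, choosing the brightest probe per gene did not apply.

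Mean signals and local backgrounds were corrected with the normexp model, with 50 added afterwards, then normalized by loess within each array, with control spots at weight 0. The model had been planned on all spots. On ∆gprH 8 h array 1 a few spots with local backgrounds up to 65535 distorted that fit, which gave a standard deviation of 497 for the Cy3 background there and a median absolute deviation of the log2 ratios of 0.126. After seeing this, the model was fitted without spots whose local background exceeded 2 times the array's median, between 0 and 16 spots per array, which brought that median absolute deviation to 0.633. The other arrays lay between 0.537 and 0.741. R21 8 h array 1, with local backgrounds up to 3969, was distorted too: the standard deviation of its Cy5 background was 46.8 on all spots and 2.58 without those spots. Those spots and spots marked as outliers, 2.85% to 4.08% per array, were left out, and spots of a gene were averaged. Saturated spots were kept. Median signals per array were 108 to 175 in Cy3 and 298 to 576 in Cy5, over backgrounds of 37 to 40.5. Genes were tested where, in at least 1 group, every array showed the gene well above background in a channel, which left 8655. For the glucose-medium comparison the channels were separated after Aquantile normalization between arrays, and the 2 glucose channels of a strain that share a replicate number were averaged, giving 18 RNA samples in 6 groups.

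Linear models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, all 12 arrays in 1 fit of 4 group means (8 residual degrees of freedom) and Benjamini-Hochberg adjustment at a threshold of 0.05 within each of 10 comparisons. These were the response of each strain at 4 h and 8 h, 8 h against 4 h in each strain, the strain difference of the response at 4 h, at 8 h and as their mean, and the strain difference in glucose medium. All tests were two-sided. Files were read with jsonlite 2.0.0 and version 1.17.8 of data.table, and figures drawn with matplotlib 3.10.9 in python 3.11.15. The design, the alternatives, the rule for named genes and the first 16 gene lists were fixed before the data were examined. The other 14 lists, from proteasome to septins, used reference symbols and were written after the reference table and summary statistics of the files had been seen but before any gene's expression was looked at. Lists searched by product name could not be built, as the reference holds no product names, and were not run.

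Named genes are gprH, then, among genes with a symbol, an adjusted p under the threshold and arrays that all changed the same way (or, between groups, did not overlap), the 6 largest rises and falls of each response and time comparison and the 10 largest of each strain difference, then up to 4 passing members of each list with the largest changes. By chance 10% of genes do not overlap between 3 and 3 arrays. Members of the glyoxylate, glycolysis, receptor and development lists could also be named as not passing. Of 30 lists with 355 members on the array and 334 tested, 29 had at least 4 tested members and were tested as sets with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The cluster lists are runs of neighbouring loci. A gene not well above background on any array of a group is given only as a bound.

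Whether replicate numbers pair the arrays was checked on deviations from the group means. Within a strain, 4 h and 8 h arrays of the same number correlated across genes with r between 0.134 and 0.407 (median 0.305). Those of different numbers had r between −0.532 and 0.25 (median −0.203). In R21 the ranges overlapped: array 3 at 4 h had r = 0.134 with array 3 and 0.25 with array 1 at 8 h. The numbers were taken to pair 4 h with 8 h arrays of a strain, more clearly in ∆gprH, possibly through a shared glucose-grown RNA. Across strains the same check gave r between −0.29 and 0.399, so they do not pair the strains.

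The linear fits, and the list test at its preset correlation, were tested on simulated gene values with independent errors. Background correction, normalization, the filter, the bounds and the estimated correlation were not simulated. In each fit 66 or 67 of 8655 genes were changed per size of change, far fewer than the data called. For the R21 response at 4 h, 80.6% of genes simulated with a log2 change of 0.5, 98.5% of those with 1 and 100% of those with 2 were called. For 8 h against 4 h in R21 these shares were 44.8%, 98.5% and 100%, and for the strain difference at 4 h 53.7%, 98.5% and 100%. False calls made up 2.33% to 7.73% of the calls, depending on the comparison. A shift of 0.5 in the proteasome list was found in 20 of 20 simulations, with 1 call among 560 tests of other lists. Alternatives were Agilent's log ratios, the deposited value table, median centring, equal spread, no filter on dim genes, slide as a fixed or random block or within a slide, the replicate number as a block, the compared groups alone and leaving out each array, and for the glucose channels quantile normalization of processed signals, median scaling and other treatments of the paired channels. Fits of the background model on all spots and of the glucose channels of 4 h or 8 h arrays alone were added after seeing the data. No 2 arrays held identical values.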

Results

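Transcript levels were measured on 12 2-colour arrays of the filamentous fungus Aspergillus nidulans, in strain R21 and in a strain with the gene gprH deleted (∆gprH). gprH encodes a predicted G-protein-coupled receptor. Mycelium grown for 24 h in minimal medium with glucose was moved to the same medium without a carbon source for 4 h or 8 h. Each strain and time had 3 arrays. Per the channel labels, the Cy5 channel of every array held starved RNA and the Cy3 channel held glucose-grown RNA of the same strain, so a positive log2 ratio means more transcript after starvation. Dyes were never swapped, so a gene's dye bias stays in each starvation response but cancels in a difference between groups of arrays. Between 54.5% and 74.0% of the 11143 genes were well above background in the glucose channel of an array, and between 57.6% and 78.5% in the starved channel. Saturation affected 0 genes in the glucose channel and 6 to 15 genes per array in the starved channel. The number of arrays limits the precision of every value.

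Across genes, log2 ratios of arrays of 1 group correlated with r between 0.965 and 0.993, and those of different strains with r between 0.664 and 0.753, where genes are not independent replicates. The first principal component held 74.3% of the variance and separated the strains, and the next held 12.8% and separated 4 h from 8 h. The arrays lay on 3 slides. Slide 1 held all R21 4 h arrays and 1 R21 8 h array, slide 2 held the other R21 8 h arrays and 2 ∆gprH 4 h arrays, and slide 3 held the remaining ∆gprH 4 h array and all ∆gprH 8 h arrays. No slide held both strains at the same starvation time. Within slide 1 a single array stands for R21 at 8 h, and within slide 3 a single array for ∆gprH at 4 h. With slide as a block each time difference comes from that slide alone, so slide-block and within-slide values of a time difference below are the same check. A slide-block strain difference starts from ∆gprH at 4 h against R21 at 8 h on slide 2. It is carried to 4 h by the R21 time difference on slide 1, or to 8 h by that of ∆gprH on slide 3. Slide-block strain differences thus rest on those single arrays too, and do not compare the strains at 1 time within a slide. Values below are log2(starved/glucose) as mean ± SD over n = 3 arrays, or log2 differences between groups with their standard error (SE). Adjusted p-values are from limma over 8655 tested genes. Genes were chosen for naming among those with a symbol and the members of gene lists, so genes without either can have larger changes.

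The gprH probe was read first. In R21 its starved channel was well above background on 6 of 6 arrays, with mean signals from 4113 to 6043 at 4 h and from 2989 to 4532 at 8 h. The R21 glucose channel of gprH, with signals from 51.6 to 57.8, was not well above background on any array, so its transcript was at least 22.5-fold higher after 4 h of starvation (adjusted p = 9.63e-10) and at least 13.4-fold higher after 8 h (adjusted p = 3.55e-09). In ∆gprH the starved channel was not well above background on any of 6 arrays, with signals from 47.2 to 86.7. R21 exceeded ∆gprH in that channel by at least 25-fold at 4 h and at least 20.2-fold at 8 h. The glucose channel of ∆gprH gave a signal well above background on all 6 arrays, from 133 to 246, at least 2.01-fold above that of R21 (adjusted p = 6.92e-05), which the deletion does not lead one to expect. It exceeded the starved channel of the same arrays by at least 2.47-fold at 4 h and at least 2.75-fold at 8 h. Between 8 h and 4 h the R21 log2 ratio, whose glucose channel is only a bound, differed by −0.75 (SE 0.27, adjusted p = 0.0591), and it passed with a replicate block (adjusted p = 0.0308). The files do not say whether the probe lies in the deleted part of the gene. Each "at least" fold sets the mean of the brighter group against a bound for the dimmer group, per channel after loess and Aquantile normalization. The bound is, per array, the higher of the lowest signal that counted as above background and the gene's own signal. For gprH in R21 its own signal was the higher, so the bound equals the fitted fold. Folds of one channel over the other remain open to dye bias.

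**Figure D1:**
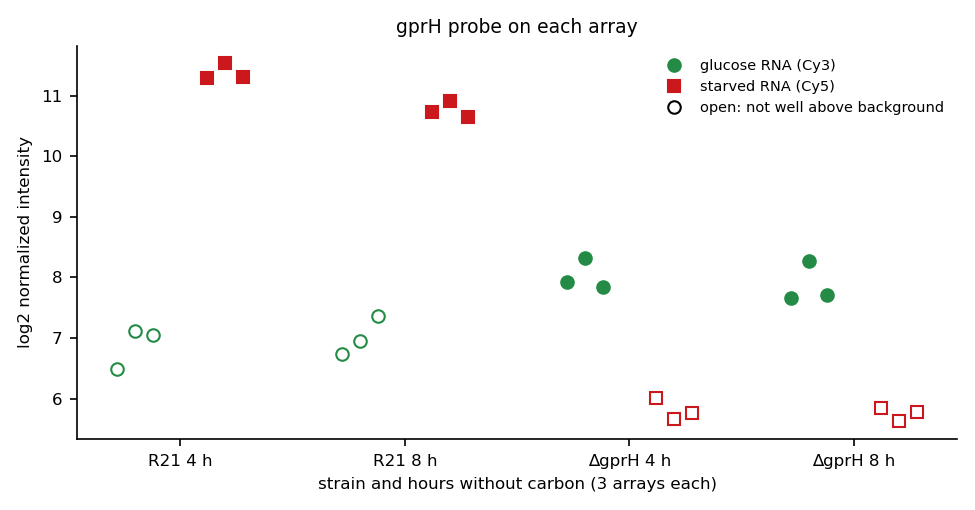
Normalized log2 intensity of the gprH probe (vertical axis) in the glucose channel (circles, Cy3) and the starved channel (squares, Cy5) of the 3 arrays of each strain and time, with open symbols where the probe was not well above background. The starved channel lay between 10.6 and 11.5 in R21 and between 5.63 and 6.02 in ∆gprH.

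The first comparison asks how R21 responded to 4 h without carbon. Among genes for the use of other carbon sources, aldA and alcA, the aldehyde and alcohol dehydrogenases of ethanol use, rose by 6.26 ± 0.57 (n = 3) and 5.85 ± 0.45, and facA, which makes acetyl-CoA from acetate, by 3.70 ± 0.12 (adjusted p = 4.33e-10). acuF, the first enzyme of gluconeogenesis, rose by 2.58 ± 0.23, and the glyoxylate cycle enzymes acuD and acuE rose by 1.34 ± 0.29 and 1.29 ± 0.21. Genes of amino acid breakdown that rose were prnD of proline use at 3.72 ± 0.35 (adjusted p = 3.74e-10), fahA of phenylalanine and tyrosine use at 3.93 ± 0.64 (adjusted p = 6.41e-09) and gdhB, the catabolic glutamate dehydrogenase, at 3.19 ± 0.32. Other rises were kat1 at 3.76 ± 0.29, gta1 at 3.57 ± 0.12 and ivoB, a gene of conidiophore pigment, at 4.76 ± 0.17 (adjusted p = 1.28e-09). Of the nitrate genes, the transporter crnA was at −4.08 ± 0.08 (adjusted p = 2.08e-10), the nitrite reductase niiA at −3.60 ± 0.53 and the nitrate reductase niaD at −3.20 ± 0.49. The chitinase gene chiA1 at −3.72 ± 0.27, the catalase gene cat1 at −3.69 ± 0.23 (adjusted p = 1.09e-11), sur2 at −3.40 ± 0.11 and sxa2 at −3.76 ± 0.18 fell too. Of the 8655 genes, 3751 rose and 3424 fell, of which 1294 rose and 1344 fell at least 2-fold.

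Lists of genes were tested as sets with camera. Of 10 glycolysis genes 9 fell and 1 rose in R21 at 4 h (median −1.86, adjusted p = 0.003), with glkA, the glucokinase, at −3.10 ± 0.18 and pfkA, the phosphofructokinase, at −3.07 ± 0.27. Of 18 amino acid synthesis genes 17 fell (median −1.54, adjusted p = 5.96e-05), with met16 at −3.09 ± 0.21 and ilv3 at −2.83 ± 0.06. Of 16 ergosterol synthesis genes 11 fell and 1 rose (median −0.73, adjusted p = 0.0183), with erg1 at −2.23 ± 0.27. The 4 trehalose genes fell (median −1.29, adjusted p = 0.0408), among them the synthase tpsA at −1.88 ± 0.14, and so did the 5 translation initiation genes (median −0.77, adjusted p = 0.0426). Rises were seen in the 4 autophagy genes (median 1.07, adjusted p = 0.0408), with atg8 at 1.49 ± 0.03, and in the 5 autolysis genes (median 1.41, adjusted p = 0.0408), with the autolytic chitinase chiB at 3.60 ± 0.66 and the protease prtA at 2.81 ± 0.18. Of 15 proteasome genes 14 rose (median 0.59, adjusted p = 0.00366), with pup1 at 1.21 ± 0.09. These calls rest on a small preset correlation between genes. For glycolysis, amino acid synthesis, ergosterol, trehalose, autophagy and autolysis the result was adjusted p = 0.434 with an estimated correlation, for the proteasome adjusted p = 0.611 with an estimated correlation, and for translation initiation adjusted p = 0.621 with an estimated correlation. Counts adjusted over the list alone were the same for these 8 lists.

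The other lists were not called in R21 at 4 h, though single members changed. In the list of glyoxylate cycle, acetate use and gluconeogenesis 7 of 9 rose and 2 fell (adjusted p = 0.109), and in ethanol use 7 of 9 rose and 2 fell (adjusted p = 0.136). Among asexual development genes 6 of 17 rose and 7 fell (adjusted p = 0.98, median 0.00 against a mean of 0.11), with conF at −3.83 ± 0.29 and the regulator stuA at 2.96 ± 0.05. Among sexual development genes 11 of 17 rose and 4 fell (adjusted p = 0.14), with ppoC at 2.42 ± 0.26 and veA at 1.93 ± 0.11. Among receptor genes 8 of 12 rose and 4 fell (adjusted p = 0.462), with gprF at −2.19 ± 0.10 and the opsin gene nopA at −2.24 ± 0.40, and among G protein and cAMP signalling genes 2 of 13 rose and 6 fell (adjusted p = 0.412). In the sterigmatocystin cluster 4 of 21 rose and 3 fell (adjusted p = 0.962), or 3 and 2 adjusted over the list alone, with a median of 0.07 against a mean of −0.11. In other secondary metabolite clusters 10 of 19 rose and 2 fell (adjusted p = 0.136), among plant polysaccharide genes 8 of 15 rose and 4 fell (adjusted p = 0.342) and among hexose transporters 3 of 5 rose and 2 fell (adjusted p = 0.744), with hxtA at 3.73 ± 0.29 and the low-affinity transporter mstE at −3.75 ± 0.61. Among stress genes 3 of 8 rose and 5 fell (adjusted p = 0.462) and among nitrogen genes 3 of 13 rose and 9 fell (adjusted p = 0.135). Ribosomal protein genes (0 of 8 rose and 5 fell, adjusted p = 0.14), ribosome assembly genes (4 of 24 rose and 13 fell, adjusted p = 0.14) and septin genes (0 of 5 rose and 4 fell, adjusted p = 0.14) were not called either. The same held for peroxisome assembly (8 of 12 rose and 1 fell, adjusted p = 0.14), wall synthesis (8 of 16 rose and 6 fell, adjusted p = 0.914, median 0.21 against a mean of −0.11), autophagy genes with reference symbols (5 of 5 rose and 0 fell, adjusted p = 0.0827), chaperones (6 of 11 rose and 5 fell, adjusted p = 0.99, median 0.26 against a mean of −0.03), iron uptake (7 of 12 rose and 0 fell, adjusted p = 0.306, or 6 and 0 adjusted over the list alone) and the secretory pathway (5 of 8 rose and 0 fell, adjusted p = 0.122). Of 3 zinc uptake genes, too few for a set test, 3 fell. With median centring in place of loess the medians of the asexual development, G protein, sterigmatocystin, other secondary metabolite, ribosome assembly and septin lists changed sign, to 0.50, 0.54, −0.54, −0.32, 0.11 and 0.22.

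The next comparison asks what R21 looked like after 8 h. Spore and conidiophore genes that rose were the pigment genes ivoA at 4.97 ± 0.44 (adjusted p = 3.52e-11) (n = 3) and ivoB at 4.91 ± 0.21, and rodA, the hydrophobin of conidia, at 4.71 ± 0.34 (adjusted p = 2.65e-10). brlA, the central regulator of conidiation, was 3.65 ± 0.51 with its glucose channel above background on 1 of 3 arrays, after at least 6-fold higher in starved RNA at 4 h. The asexual development list was not called (adjusted p = 0.239), and its member conF fell, to −4.60 ± 0.34. aldA stayed high at 5.04 ± 0.48, and facA and acuF at 3.28 ± 0.13 and 2.35 ± 0.13, while the glyoxylate cycle enzyme acuE (−0.12 ± 0.41, adjusted p = 0.442) did not pass the test. The nitrate genes niiA and crnA stayed low, at −4.40 ± 0.18 (adjusted p = 3.84e-10) and −4.21 ± 0.18, as did cat1 at −4.26 ± 0.05 (adjusted p = 5.35e-12), chiA1 at −3.87 ± 0.07 and the alpha-glucan synthase ags1 at −4.00 ± 0.20. The sexual development genes mutA and esdC were at 3.47 ± 0.33 and 2.69 ± 0.14. Of 8655 genes, 3702 rose and 3439 fell, of which 1340 rose and 1391 fell at least 2-fold.

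In R21 at 8 h 9 of 10 glycolysis genes fell and none rose (median −1.84, adjusted p = 0.00353), with pfkA at −3.94 ± 0.11. Amino acid synthesis fell in 14 of 18 genes and rose in 1 (median −0.86, adjusted p = 0.00353). The 5 autolysis genes rose (median 3.46, adjusted p = 0.0181), with chiB at 4.93 ± 0.28, and the 4 autophagy genes rose (median 1.33, adjusted p = 0.0357). In other secondary metabolite clusters 15 of 19 rose and 1 fell of the measured genes (median 0.93, adjusted p = 0.0172). For autolysis the result was adjusted p = 0.551 with an estimated correlation, and for the remaining 4 lists adjusted p = 0.58 with an estimated correlation. Counts adjusted over the list alone were the same for these 5 lists. The 24 other lists were not called.

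In ∆gprH the largest rise after 4 h without carbon, among genes with a symbol, was dppV, a secreted dipeptidyl peptidase, at 7.0 ± 0.53 (adjusted p = 9.16e-11) (n = 3), and dppIV of the same enzyme class rose by 4.20 ± 0.41. Of the genes of the sexual cycle, esdC rose by 4.39 ± 0.17 (adjusted p = 1.52e-10), the pheromone receptor gene preA by 4.12 ± 0.07 (adjusted p = 5.6e-12), with its glucose channel above background on 2 of 3 arrays, and ppoC by 1.79 ± 0.16. The formate dehydrogenase gene fdh rose by 4.59 ± 1.15, kat1 by 4.16 ± 0.33, facA by 3.58 ± 0.48, and aldA and alcA by 5.48 ± 0.79 and 4.96 ± 1.11. The alpha-glucosidase gene agdA rose by 4.34 ± 0.22. The glyoxylate cycle enzyme acuE fell, at −0.88 ± 0.22. Falls included crnA at −4.01 ± 0.46, pyroA of vitamin B6 synthesis at −3.41 ± 0.12, niiA at −3.20 ± 0.32, the citrate synthase gene cit1 at −3.19 ± 0.20 and ilv3 of branched-chain amino acid synthesis at −3.03 ± 0.15. Of 8655 genes, 3903 rose and 3474 fell, of which 1585 rose and 1384 fell at least 2-fold. The share of rises, 52.9%, was 48.8% with Agilent's log ratios.

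Protein synthesis genes fell as groups in ∆gprH at 4 h. All 24 tested ribosome assembly genes fell (median −1.23, adjusted p = 4.97e-07, and adjusted p = 0.415 with an estimated correlation), with nop7 at −2.61 ± 0.24 and cbf5 at −2.47 ± 0.23. The 8 ribosomal protein genes fell (median −0.80, adjusted p = 0.041, and adjusted p = 0.625 with an estimated correlation), and so did the 5 translation initiation genes (median −1.49, adjusted p = 0.0115, and adjusted p = 0.441 with an estimated correlation). All 18 amino acid synthesis genes fell (median −1.69, adjusted p = 4.54e-07), all 10 glycolysis genes fell (median −1.85, adjusted p = 0.000562), and 14 of 16 ergosterol genes fell (median −0.77, adjusted p = 0.000575). Nitrogen genes fell in 9 of 13 cases and rose in 2 (median −0.45, adjusted p = 0.0398). The 5 autolysis genes rose (median 3.62, adjusted p = 0.0171). For these 5 lists the result was adjusted p = 0.343 with an estimated correlation. The 4 autophagy genes rose (median 1.18, adjusted p = 0.0275), and 14 of 17 sexual development genes rose and 3 fell (median 0.72, adjusted p = 0.0208), each with adjusted p = 0.347 with an estimated correlation. In the sterigmatocystin cluster 19 of 21 genes rose (median 0.82, or 0.67 with genes not above background set at their bound, adjusted p = 0.00662), and 13 of 15 proteasome genes rose (median 0.40, adjusted p = 0.0171), each with adjusted p = 0.625 with an estimated correlation. Counts adjusted over the list alone were the same for these 12 lists.

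After 8 h in ∆gprH, members of the sterigmatocystin cluster, which makes a polyketide mycotoxin, were among the rises: AN7825 rose by 7.30 ± 0.38 (adjusted p = 4.25e-11), AN7821 by 7.21 ± 0.29 (adjusted p = 3.34e-12), AN7812 by 6.63 ± 0.35 and AN7809 by 6.48 ± 0.32 (n = 3). tpcL rose by 6.75 ± 0.36 (adjusted p = 2.14e-11), dppV by 6.36 ± 0.23, gta1 by 4.91 ± 0.18, hmgX by 4.57 ± 0.36 and fdh by 4.42 ± 0.96. Of the sexual development genes, esdC was at 4.41 ± 0.49, mutA at 4.01 ± 0.38 and preA at 3.93 ± 0.27. The conidiophore gene ivoB reached 4.09 ± 0.20, and rodA 2.10 ± 0.38 with its glucose channel above background on 2 of 3 arrays. acuF and facA were at 3.29 ± 0.07 and 2.55 ± 0.24, whereas alcA (−0.12 ± 0.11, adjusted p = 0.776) did not pass the test. crnA, niiA, cit1 and ags1 were low, at −4.40 ± 0.25, −3.91 ± 0.23, −3.32 ± 0.09 and −3.19 ± 0.18. Of 8655 genes, 3891 rose and 3530 fell, of which 1723 rose and 1369 fell at least 2-fold. The share of rises, 52.4%, was 49.1% with Agilent's log ratios.

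In ∆gprH at 8 h all 21 sterigmatocystin cluster genes rose (median 5.43, or 5.39 with genes not above background at their bound, adjusted p = 2.54e-08), as did 17 of 19 genes of other secondary metabolite clusters, where 1 fell (median 1.00, adjusted p = 0.00484). The 5 autolysis genes rose (median 3.37, adjusted p = 0.0161), and so did the 4 autophagy genes (median 1.51, adjusted p = 0.0238) and 12 of 17 sexual development genes, where 2 fell (median 0.74, or 0.66 with genes at their bound, adjusted p = 0.0238). All 18 amino acid synthesis genes fell (median −1.43, adjusted p = 7.19e-07), with 9 of 10 glycolysis genes (median −2.02, adjusted p = 0.000892), 15 of 16 ergosterol genes, where 1 rose (median −0.80, or −0.75 with genes at their bound, adjusted p = 0.00131), and 11 of 13 nitrogen genes, where 2 rose (median −0.54, adjusted p = 0.0355). For these 9 lists the result was adjusted p = 0.302 with an estimated correlation. All 24 ribosome assembly genes fell (median −1.25, adjusted p = 1.18e-06, and adjusted p = 0.353 with an estimated correlation), as did the 5 translation initiation genes (median −1.35, adjusted p = 0.0153, and adjusted p = 0.383 with an estimated correlation). Of 15 proteasome genes 13 rose and 1 fell (median 0.41, adjusted p = 0.0427, and adjusted p = 0.705 with an estimated correlation). Counts adjusted over the list alone were the same for these 12 lists.

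**Figure D2:**
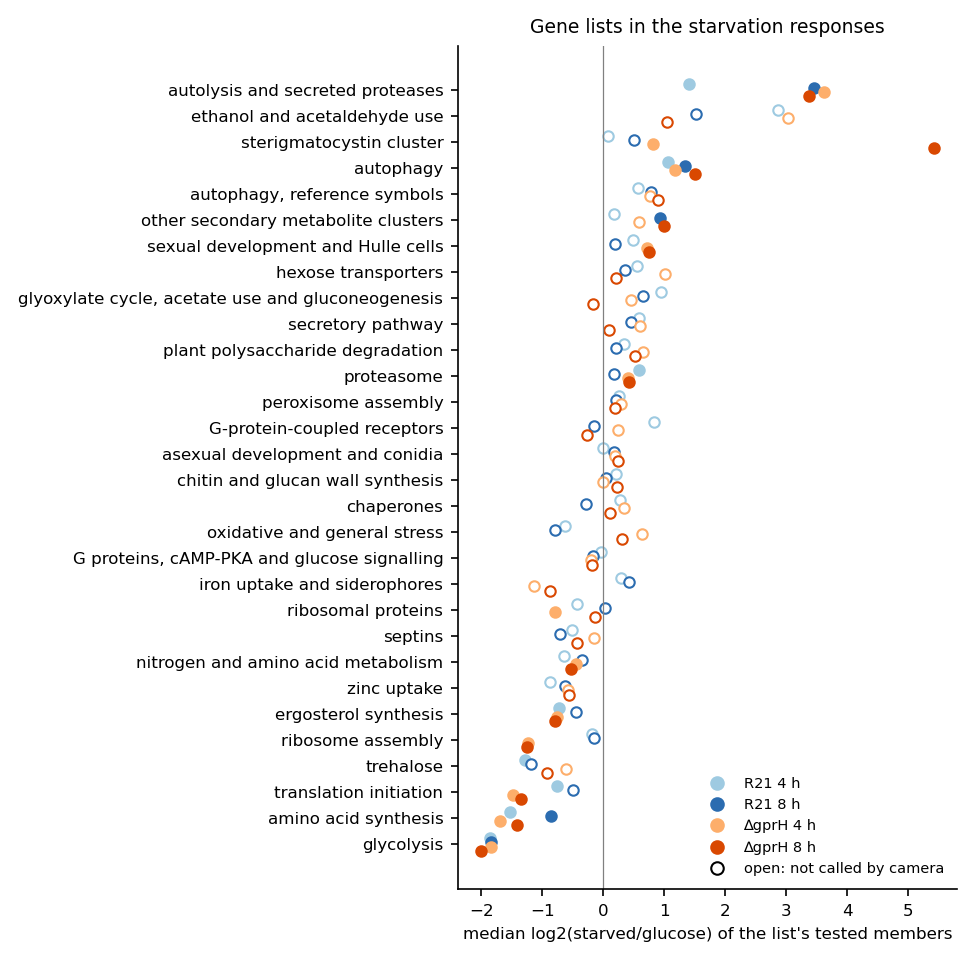
Median log2(starved/glucose) of the tested members of each gene list (horizontal axis) in the 4 starvation responses, with filled points where camera called the list at its preset correlation. Glycolysis and amino acid synthesis lay below 0 in all 4 responses, at −1.86 and −1.54 in R21 at 4 h, and the sterigmatocystin cluster reached 5.43 in ∆gprH at 8 h.

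The responses of the strains shared many calls. At 4 h 2932 genes rose and 2587 fell in both strains, where independent lists of these sizes would share 1691.5 and 1374.3, and 751 genes went opposite ways. Across genes, which are not independent replicates, the responses correlated with r = 0.711 at 4 h and r = 0.739 at 8 h. At 8 h 2960 genes rose and 2667 fell in both, against 1664.3 and 1402.6, and 680 went opposite ways. Shared rises included aldA, facA and kat1, and shared falls included crnA, niiA and glkA. Within R21 the 4 h and 8 h responses shared 3226 rises and 3033 falls (1604.4 and 1360.5 for independent lists), with r = 0.922 and a covariance of 1.52. Within ∆gprH they shared 3563 rises and 3201 falls (1754.7 and 1416.9), with r = 0.949 and a covariance of 1.80. Simulated responses without any effect that shared 3 glucose-grown RNAs gave a mean r of 0.354 and a covariance of 0.00621. Part of the excess within a strain may come from shared controls, as 4 h and 8 h arrays of 1 strain may carry the same glucose-grown RNAs. By the simulated covariance of 0.00621 that part would be small beside 1.52 and 1.80. With dyes never swapped, a gene's dye bias enters all 4 responses with the same sign. It can add to the shared calls and to r, between strains as well as between times. The counts for independent lists leave it out, and its share was not tested.

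The comparison of 8 h with 4 h asks how starvation progressed in R21. The conidiation gene ivoA was higher at 8 h by 5.32 (SE 0.19, adjusted p = 3.39e-08), though it was above background on only 2 of 3 arrays at 4 h, rodA by 3.87 (SE 0.25, adjusted p = 1.46e-06), with its glucose channel above background on 2 of 3 arrays at 4 h, and ccpA by 3.38 (SE 0.34, adjusted p = 3.49e-05). The spore gene conJ was higher by 3.71 (SE 0.75, adjusted p = 0.00362) and the conidial pigment gene yA by 1.32. The leucine synthesis gene luA rose by 1.60 and trpB of tryptophan synthesis by 1.15. Lower at 8 h were aspf4 by −2.41 (SE 0.11, adjusted p = 1.47e-07), tmpA, an oxidoreductase linked to conidiation, by −2.08 and fhpA by −1.58. alcA was lower by −2.11 and the receptor gene gprK by −1.90. Of 8655 genes, 1165 were higher and 1341 lower at 8 h, of which 236 and 230 changed at least 2-fold. Without R21 8 h replicate 1 the total of 2506 was 1656, and 1070 with the background model on all spots, a fit distorted on that same array. Within slide 1, with a single 8 h array, and so also with slide as a block, 1759 genes passed.

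In R21 the 5 autolysis genes were higher at 8 h (median 1.15, adjusted p = 0.00237, and adjusted p = 0.439 with an estimated correlation), with 1.12 when slide was a block and also within slide 1. Of 17 asexual development genes 8 were higher and 2 lower, or 9 and 2 adjusted over the list alone (median 0.26, adjusted p = 0.00237, slide-block and within-slide median 0.45), and 13 of 15 proteasome genes were lower, or 14 adjusted over the list alone (median −0.39, adjusted p = 3.72e-06, slide-block and within-slide median −0.39). Of 12 receptor genes 5 were lower, or 6 adjusted over the list alone (median −0.49, adjusted p = 0.0154, slide-block and within-slide median −0.56). For these 3 lists the result was adjusted p = 0.494 with an estimated correlation. Of 9 ethanol use genes 6 were lower (median −0.75, adjusted p = 0.0154, slide-block and within-slide median −0.94), with adjusted p = 0.833 with an estimated correlation. Of 15 plant polysaccharide genes 5 were lower (median −0.19, adjusted p = 0.0458, slide-block and within-slide median −0.26), with adjusted p = 0.439 with an estimated correlation. Higher at 8 h were 7 of 18 amino acid synthesis genes (median 0.21, adjusted p = 0.0037, slide-block and within-slide median 0.23), with adjusted p = 0.77 with an estimated correlation. In the sterigmatocystin cluster 7 of 21 genes were higher (median 0.37, adjusted p = 0.00529, slide-block and within-slide median 0.47), and 2 of 8 ribosomal protein genes were higher, or 0 adjusted over the list alone (median 0.43, adjusted p = 0.0458, slide-block and within-slide median 0.51), both with adjusted p = 0.856 with an estimated correlation.

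In ∆gprH the sterigmatocystin cluster rose from 4 h to 8 h. AN7825 was higher at 8 h by 6.48 (SE 0.31, adjusted p = 9.85e-08), and AN7805, chosen after its values were seen, by 4.20 (SE 0.14, adjusted p = 4.94e-09). AN7807 was not well above background on any array at 4 h and was at least 45-fold higher in starved RNA at 8 h. Of its 21 genes 19 were higher, or 20 adjusted over the list alone (median 4.59, adjusted p = 4.83e-37, and adjusted p = 0.112 with an estimated correlation), with a median of 4.78 within slide 3, with its single 4 h array, and so also with slide as a block, and 5.42 in starved RNA with genes at their bound. Also higher were rodA by 1.61 (SE 0.25, adjusted p = 0.00147), with its glucose channel above background on 1 of 3 arrays at 4 h and 2 of 3 at 8 h, acuF by 1.53 (SE 0.23, adjusted p = 0.00149) and smp3 by 1.32. The rodA value did not pass with Agilent's log ratios, at 1.54 with adjusted p = 0.0595, or with the background model on all spots, at 1.14 with adjusted p = 0.219. Lower at 8 h were alcA by −5.08 (SE 0.52, adjusted p = 0.000125) and the endoplasmic reticulum chaperones clxA by −1.30 and pdiA by −1.22. Of 8655 genes 818 were higher and 569 lower, of which 137 and 89 changed at least 2-fold. The share of higher calls, 59.0%, was 36.7% with the background model on all spots, 49.6% with Agilent's log ratios and 79.2% with slide as a block, so its direction is not settled. With slide as a block, and so within slide 3, 476 genes passed, and 683 passed when only these 6 arrays were fitted, 256 with the background model on all spots, and 847 and 913 without ∆gprH 8 h replicate 2 or 3.

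Other lists that shifted between 4 h and 8 h in ∆gprH were ethanol use, where 7 of 9 genes were lower and 1 higher (median −1.22, adjusted p = 0.00226, slide-block and within-slide median −0.96), and other secondary metabolite clusters, where 5 of 19 were higher (median 0.29, adjusted p = 0.00922, slide-block and within-slide median 0.47). Lower were 4 of 8 secretory pathway genes, or 5 adjusted over the list alone (median −0.45, adjusted p = 0.00226, slide-block and within-slide median −0.40), 2 of 13 G protein and cAMP genes, or 4 adjusted over the list alone (median −0.20, adjusted p = 0.0366, slide-block and within-slide median −0.20), and 1 of 5 septin genes, or 2 adjusted over the list alone (median −0.25, adjusted p = 0.0266, slide-block and within-slide median −0.45). For these 5 lists the result was adjusted p = 0.565 with an estimated correlation. Lower too were 3 of 4 trehalose genes (median −0.43, adjusted p = 0.0144, slide-block and within-slide median −0.37, and adjusted p = 0.443 with an estimated correlation) and 3 of 11 chaperone genes, or 4 adjusted over the list alone (median −0.35, adjusted p = 0.00226, and adjusted p = 0.45 with an estimated correlation). The chaperone median shrank to −0.05 with slide as a block and within slide 3. Of 8 ribosomal protein genes 1 was higher, or 6 adjusted over the list alone (median 0.54, adjusted p = 0.00922, slide-block and within-slide median 0.26, and adjusted p = 0.644 with an estimated correlation).

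The central comparison asks how the deletion of gprH altered the starvation response, as the log2 ratio of ∆gprH minus that of R21. At 4 h dppV differed by 7.22 (SE 0.32, adjusted p = 7.65e-09), chiA1 by 6.51 (SE 0.17, adjusted p = 1.89e-10) and cat1 by 5.01 (SE 0.11, adjusted p = 8.68e-11): chiA1 was −3.72 ± 0.27 in R21 and 2.79 ± 0.36 in ∆gprH (n = 3 each), and cat1 −3.69 ± 0.23 and 1.32 ± 0.04. The mating genes ppgA, a pheromone precursor, and preA, a pheromone receptor, differed by 6.08 and 4.63, with the ∆gprH glucose channel above background on 2 of 3 arrays for each. agd3, an enzyme for a wall polysaccharide, differed by 4.59, the transcription factor atfB by 4.01 (SE 0.14, adjusted p = 1.24e-09), the histidine kinase tcsB by 3.62 and the trehalase treA by 3.11. Lower responses in ∆gprH were those of the siderophore synthesis gene sidD by −3.56 (SE 0.31, adjusted p = 1.87e-06), the siderophore transporter sit1 by −2.48, tmpA by −3.00 (SE 0.21, adjusted p = 3.9e-07) and the proline permease prnB by −2.91. The glyoxylate cycle enzymes acuE and acuD were lower by −2.17 (adjusted p = 2.44e-06) and −1.64 (adjusted p = 8.65e-05). Among receptor genes nopA differed by 1.72, and in cAMP signalling pkaR and pkaC differed by 1.18 and 1.17. Neither the receptor list nor the G protein and cAMP list was called, and their medians were −0.045 and −0.198, opposite in sign to these genes. Of 8655 genes 2883 had a higher and 2594 a lower response in ∆gprH, of which 947 and 530 differed at least 2-fold. The share of higher calls, 52.6%, turned to 44.1% with Agilent's log ratios and 42.6% with median centring. With slide as a block 3200 genes passed.

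The differences were split by channel. Of the 947 genes at least 2-fold higher at 4 h, 587 differed in both channels, 224 in the starved channel alone, 131 in the glucose channel alone and 5 in neither. For the 530 lower genes these counts were 287, 196, 44 and 3. chiA1 was lower by −4.79 (SE 0.14) in the glucose channel of ∆gprH and higher by 1.85 (SE 0.14) in its starved channel at 4 h. In the glucose channel dppV and agd3 were lower by −4.51 and −4.23. A large part of the differences of these 3 genes thus lay in glucose-grown RNA.

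As groups, ribosome assembly genes had a lower response in ∆gprH at 4 h in 24 of 24 cases (median −1.08, adjusted p = 8.28e-09, slide-block median −1.15), with nop7 at −2.07 (SE 0.14, adjusted p = 1.93e-07) and erb1 at −1.65. The 5 translation initiation genes were lower (median −0.63, adjusted p = 0.0422, slide-block median −0.71), as were 10 of 12 iron uptake genes, where 1 was higher (median −1.30, adjusted p = 0.00333, slide-block median −1.17), and 11 of 18 amino acid synthesis genes, or 13 adjusted over the list alone (median −0.47, adjusted p = 0.00333, slide-block median −0.43). In the sterigmatocystin cluster 14 of 21 genes were higher (median 0.77, adjusted p = 0.00333, slide-block median 0.96), with AN7805 at 5.20 (SE 0.14, adjusted p = 1.89e-10). For these 5 lists the result was adjusted p = 0.798 with an estimated correlation. No slide held both strains at 4 h, so no within-slide value can be had.

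At 8 h the sterigmatocystin cluster differed between the strains: AN7805 differed by 8.62 (SE 0.14, adjusted p = 7.28e-12) and AN7825 by 7.86 (SE 0.31, adjusted p = 2.4e-09), and in starved RNA AN7812, AN7816 and AN7806 were not well above background in R21 and at least 395-fold, 281-fold and 246-fold higher in ∆gprH. Of the 21 genes 20 were higher (median 4.95, or 5.96 in starved RNA with genes at their bound, adjusted p = 6.4e-13, and adjusted p = 0.555 with an estimated correlation), with a slide-block median of 5.14. tpcL was at least 497-fold higher in starved RNA of ∆gprH. The conidiation genes rodA and ccpA were lower, rodA by −2.61 (SE 0.25, adjusted p = 3.38e-06) and ccpA by −3.38 (SE 0.34, adjusted p = 5.51e-06), with the rodA glucose channel above background on 2 of 3 arrays in ∆gprH. The asexual development list was not called (adjusted p = 0.469), with 7 of 17 higher and 8 lower, or 7 and 9 adjusted over the list alone, and its median turned from −0.41 to 0.18 with slide as a block. ivoA was 4.97 ± 0.44 in R21, while its glucose channel in ∆gprH was not well above background and starved RNA exceeded it by at least 1.15-fold, with adjusted p = 0.111 for that response. chiA1, dppV and cat1 again differed, by 6.0 (SE 0.17, adjusted p = 3.25e-10), 6.87 and 4.99, with agd3 at 5.50, tcsB at 4.43, sidD at −3.13 and alcA at −3.86 (adjusted p = 6.26e-05). Of 8655 genes 2957 had a higher and 2414 a lower response, of which 987 and 432 differed at least 2-fold. The share of higher calls, 55.1%, turned to 45.2% with Agilent's log ratios and 44.2% with median centring. With slide as a block 3195 genes passed, with the background model on all spots 3333, and no slide held both strains at 8 h.

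**Figure D3:**
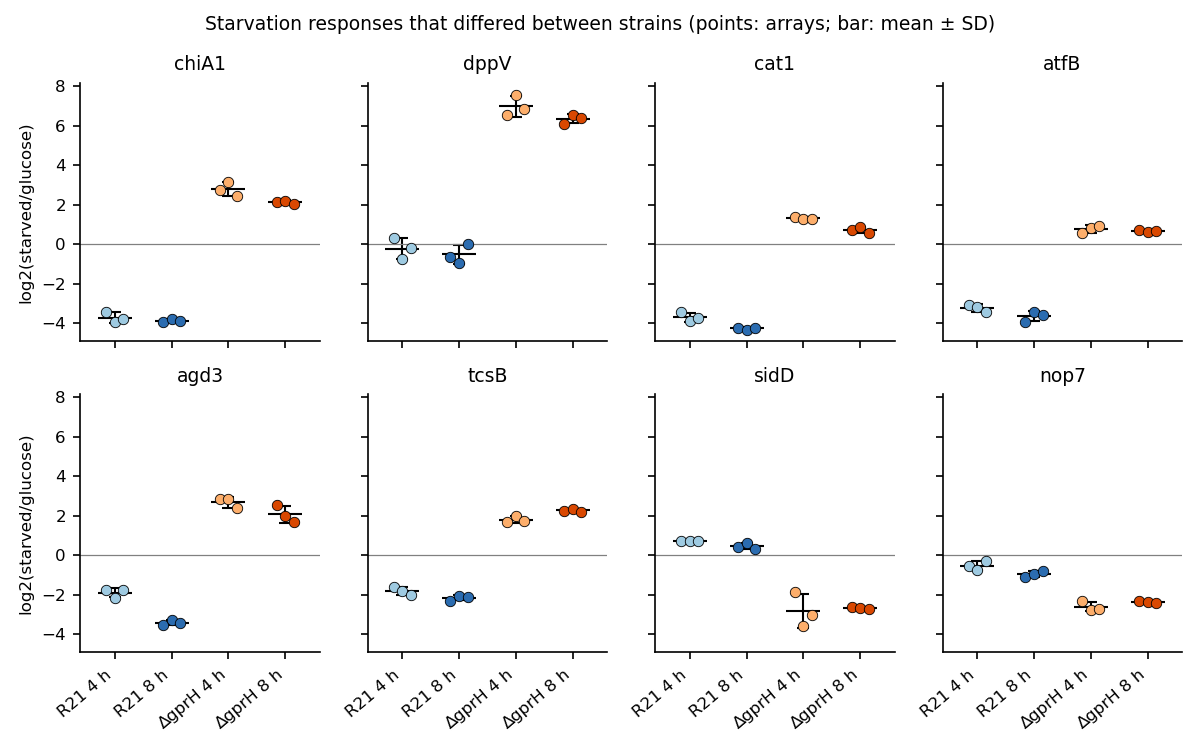
log2(starved/glucose) (vertical axis) of 8 genes with strain differences, with points for the 3 arrays of each strain and time and bars for mean ± SD. chiA1 was at −3.72 and −3.87 in R21 and at 2.79 and 2.14 in ∆gprH, and nop7 was at −2.61 and −2.37 in ∆gprH.

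Of the 987 genes at least 2-fold higher at 8 h, 551 differed in both channels, 276 in the starved channel alone, 158 in the glucose channel alone and 2 in neither. For the 432 lower genes these counts were 224, 160, 45 and 3. Ribosome assembly genes were lower in 24 of 24 cases (median −1.04, adjusted p = 2.47e-09, slide-block median −1.06, and adjusted p = 0.704 with an estimated correlation), and the 5 translation initiation genes were lower (median −0.60, adjusted p = 0.0315, slide-block median −0.70, and adjusted p = 0.83 with an estimated correlation). Of 12 iron uptake genes 11 were lower (median −1.11, adjusted p = 0.000487, slide-block median −0.90, and adjusted p = 0.728 with an estimated correlation), with sit1 at −2.25. Of 18 amino acid synthesis genes 16 were lower (median −0.66, adjusted p = 6.61e-06, slide-block median −0.76, and adjusted p = 0.555 with an estimated correlation), with trpB at −1.43 (adjusted p = 1.56e-07). Counts adjusted over the list alone were the same for the lists called at 8 h. In glucose-grown RNA the ribosome assembly, translation initiation, iron uptake and amino acid synthesis lists were higher in ∆gprH. Their medians there were 0.55, 0.40, 0.31 and 0.55, so part of these lower responses lay in glucose-grown RNA. For amino acid synthesis 0.55 exceeded in size the response difference of −0.47 at 4 h and came near the −0.66 at 8 h. Its lower response therefore need not mean a lower level in starved RNA of ∆gprH.

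**Figure D4:**
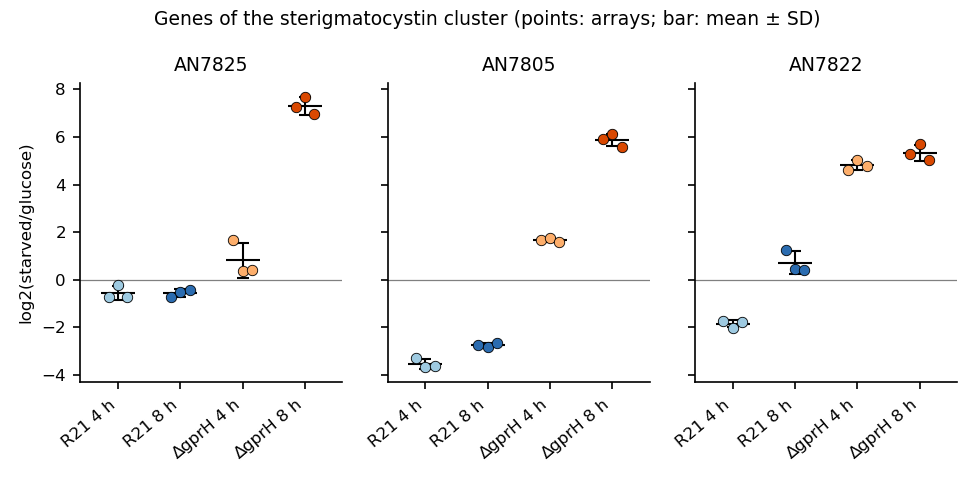
log2(starved/glucose) (vertical axis) of 3 genes of the sterigmatocystin cluster, with points for the 3 arrays of each strain and time and bars for mean ± SD. AN7825 reached 7.30 in ∆gprH at 8 h against −0.56 in R21, and AN7822 in ∆gprH at 4 h had its glucose channel above background on 2 of 3 arrays.

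The mean strain difference averages both times, so a gene that differed at 1 time alone can pass. Its SE and p-values take 4 h and 8 h arrays of a strain as independent. If replicate numbers pair these arrays, SE and p-values may be too small. dppV was at 7.05 (SE 0.23, adjusted p = 2.19e-10), chiA1 at 6.26 (SE 0.12, adjusted p = 6.66e-12), agd3 at 5.04, cat1 at 5.00 (SE 0.08, adjusted p = 1.79e-12), atfB at 4.16 and tcsB at 4.02. Lower responses were those of sidD at −3.34 (SE 0.22, adjusted p = 8.36e-08), tmpA at −2.46, sit1 at −2.36, prnB at −2.31 and nop7 at −1.75. A higher response was found in 3327 genes and a lower one in 2977, of which 959 and 422 differed at least 2-fold, and 3701 genes passed with slide as a block. The share of higher calls, 52.8%, turned to 44.1% with Agilent's log ratios and 42.7% with median centring. All 21 sterigmatocystin cluster genes were higher (median 2.90, against 0.77 at 4 h and 4.95 at 8 h, adjusted p = 1.65e-09, slide-block median 3.03), all 24 ribosome assembly genes were lower (median −1.10, adjusted p = 3.36e-09, slide-block median −1.16), and iron uptake genes were lower in 10 of 12 cases (median −1.34, adjusted p = 0.0013, slide-block median −1.12). Amino acid synthesis genes were lower in 15 of 18 cases, or 16 lower and 1 higher adjusted over the list alone (median −0.67, adjusted p = 5.96e-05, slide-block median −0.63). For these 4 lists the result was adjusted p = 0.709 with an estimated correlation. The 5 translation initiation genes were lower (median −0.63, adjusted p = 0.0287, slide-block median −0.74, and adjusted p = 0.819 with an estimated correlation).

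The last comparison asks whether the strains already differed in glucose medium, from the glucose channels alone. The unexpected gprH signal of ∆gprH in these channels limits the comparison. chiA1 was lower in ∆gprH by −4.79 (SE 0.14, adjusted p = 1.21e-13) (n = 3 RNAs per strain), dppV by −4.51 (SE 0.19, adjusted p = 9.92e-12), agd3 by −4.23 and cat1 by −2.78. The sexual development gene esdC was lower by −1.73. The iron genes sidD, sidJ and sit1 were higher in ∆gprH, sidD at 1.61 (SE 0.21, adjusted p = 1.24e-05), sidJ at 1.25 and sit1 at 1.01, as were tmpA at 1.33, prnB at 1.15 and crnA at 1.07. Of 8655 genes 1379 were higher and 1852 lower in ∆gprH, of which 110 and 380 differed at least 2-fold. The share of higher calls, 42.7%, turned to 56.9% with median scaling and 53.1% with quantile-normalized processed signals. Within slide 2, which held glucose RNA of both strains on R21 8 h and ∆gprH 4 h arrays, 2950 genes passed. That fit took the 12 glucose channels as independent and did not average paired ones, so its p-values may be too small.

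Several lists were higher in glucose-grown ∆gprH. Of 24 ribosome assembly genes 20 were higher (median 0.55, adjusted p = 7.19e-09, and adjusted p = 0.22 with an estimated correlation), with nop7 at 0.77 (SE 0.10, adjusted p = 1.09e-05) and a median of 0.62 within slide 2. Of 18 amino acid synthesis genes 16 were higher (median 0.55, adjusted p = 7.32e-07, and adjusted p = 0.162 with an estimated correlation, median 0.57 within slide 2), with lysF at 0.77 (adjusted p = 9.39e-06). The 5 translation initiation genes were higher (median 0.40, adjusted p = 0.0181, and adjusted p = 0.457 with an estimated correlation, median 0.45 within slide 2), as were 7 of 16 ergosterol genes, where 1 was lower, or 8 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.0181, and adjusted p = 0.464 with an estimated correlation, median 0.30 within slide 2). Of 12 iron uptake genes 5 were higher (median 0.31, adjusted p = 0.00669, and adjusted p = 0.545 with an estimated correlation, median 0.36 within slide 2). In the sterigmatocystin cluster 13 of 21 genes were higher and 2 lower, or 13 and 3 adjusted over the list alone (median 0.42, adjusted p = 0.0211, and adjusted p = 0.787 with an estimated correlation). That call is limited: 16 of the 21 genes had a strain whose glucose channel was not well above background, the median was 0 with those genes at their bound, 0.002 within slide 2, and 0.14 on the 4 h arrays against 0.68 on the 8 h arrays.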

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

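Among the tests in this part, the ones of the sterigmatocystin cluster and of carbon shortage were chosen only after the result was seen.

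The starvation response differed between times or strains, by a test of the difference itself, in each comparison that asked for it. Between 8 h and 4 h 2506 genes differed in R21 and 1387 in ∆gprH, with 9 gene lists called in each strain, and 0 with an estimated correlation. Between the strains 5477 genes differed at 4 h, 5371 at 8 h and 6304 in the mean of both times, with 5 gene lists called in each of these comparisons, and again 0 with an estimated correlation. Regrouping the 6 arrays of a comparison allows 10 splits, too few for a share under 0.05: the real split gave 2506, 1387, 5477 and 5371 genes and the highest other split 0 in each case. For the strain difference in glucose medium the real split of 6 RNAs gave 3231 genes and the highest other 1, again with 10 splits. For the responses, 4 sign patterns of 3 arrays are too few for such a share too: the real values were 7175, 7141, 7377 and 7421 and the highest others 0, 0, 1 and 0. For the mean strain difference, replicate numbers were taken to pair the 4 h and 8 h arrays of a strain. Splits that keep these pairs whole are again 10, too few for such a share: the real value was 6304 and the highest other 0. Of 100 splits drawn from 200 that may part the pairs, the highest other gave 2156.

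The first pattern is the rise of the sterigmatocystin cluster between 4 h and 8 h in ∆gprH, with a median of 4.59 over 21 genes. With any 1 array left out it was at least 4.39, and with Agilent's log ratios, median centring or the background model on all spots it was at least 3.82. A single array and the normalization as the whole cause are therefore argued against. Within slide 3 the median was 4.78, but that slide holds a single ∆gprH 4 h array, so the slide is not excluded and stays open. A biological difference between starvation times in ∆gprH remains open as a hypothesis, as the slide is not excluded. The list and the comparison had been fixed before the data were examined.

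The second pattern is the same cluster in the glucose channel, where ∆gprH was higher with a median of 0.42. The median was 0.14 on the 4 h arrays and 0.68 on the 8 h arrays, a ratio of 0.199, although both should carry glucose-grown RNA. Light or labelled RNA from the strong starved channel on the same array is a candidate source. Separate glucose cultures for the 4 h and 8 h arrays stay open too, so this difference is not read as expression in glucose medium.

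The third pattern is the higher level of ribosome assembly genes in glucose-grown ∆gprH, with a median of 0.55 over 24 genes. Within slide 2 the median was 0.62, which argues against the slide, and with quantile-normalized processed signals or median scaling it was at least 0.66, which argues against the channel normalization. If R21 cultures had run short of carbon, glycolysis genes might be higher in ∆gprH, as they fell more on starvation of R21 than ribosome assembly genes (medians −1.86 and −0.19 at 4 h). Their median was 0.03. The R21 medians are ratios to those same glucose cultures, so they cannot set the size of the shift. In ∆gprH glycolysis genes also fell more than ribosome assembly genes, but full starvation need not match a mild shortage. The test therefore speaks only against a shortage that acts like full starvation. The other lists called in R21 at 4 h gave mixed values in this channel. Amino acid synthesis, translation initiation and ergosterol, which fell in R21, were higher in ∆gprH, with medians of 0.55, 0.40 and 0.25. Autolysis and autophagy, which rose in R21, were lower, at −0.42 and −0.12. These go with a shortage, while trehalose at −0.27 and the proteasome at 0.11 go the other way. A partial shortage in the R21 cultures stays open. A difference in growth between the strains may underlie the pattern and was not tested.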

How the results depend on the processing

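In this part the background model on all spots, which was also run for the gene lists, and the glucose channels of 4 h or 8 h arrays alone were tests chosen only after the result was seen. Among alternative values of counts and other summary results, 150 stayed within 1.5 times the reported value and 19 did not, or, for gprH, moved by more than the spread between replicates. Alternatives that repeat or nearly repeat each other were counted separately, here and in the tally of named genes below. These were Agilent's log ratios and the deposited value table, and slide-block and within-slide fits. The cause was not tested for any of the 19, apart from a stricter minimum, which counts fewer genes by construction. With the background model fitted on all spots, which was distorted on 1 8 h array of each strain, 1070 instead of 2506 genes differed between 8 h and 4 h in R21, 256 instead of 1387 in ∆gprH, and 3333 instead of 5371 between the strains at 8 h. With slide as a fixed block these counts were 476 for 8 h against 4 h in ∆gprH, and 3200, 3195 and 3701 for the strain difference at 4 h, at 8 h and in the mean, instead of 5477, 5371 and 6304. Within slide 3, 476 genes differed between 8 h and 4 h in ∆gprH, and 683 with only these 6 arrays fitted. The gene list calls, 76 over the 10 comparisons, were 0 with an estimated correlation and 190 with fry, which asks whether a list moves and not whether it moves more than other genes. Calls shared between strains, 5519 at 4 h and 5627 at 8 h, were 1772 and 1931 with a minimum of 2-fold, and those shared between times, 6259 in R21 and 6764 in ∆gprH, were 2171 and 2644. The starved channel of gprH in ∆gprH minus R21 was −5.29, and −8.19 with quantile-normalized processed signals. Neither value is a measured size, as that channel was not well above background on any ∆gprH array.

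With 1 array left out in turn, the responses gave 6676 to 6892 genes in R21 at 4 h, 6706 to 6850 in R21 at 8 h, 7070 to 7169 in ∆gprH at 4 h and 7045 to 7141 in ∆gprH at 8 h. For 8 h against 4 h the range was 1656 to 2179 in R21 and 847 to 1688 in ∆gprH. R21 8 h replicate 1 moved the former to 1656, and ∆gprH 8 h replicates 2 and 3 moved the latter to 847 and 913. The strain differences ranged from 4873 to 5431 at 4 h, 4749 to 5031 at 8 h and 6027 to 6351 in the mean, and in glucose medium from 2531 to 2810 with 1 RNA left out. A replicate block gave 7254, 7234, 7427 and 7485 genes for the responses, 2660 and 1576 for 8 h against 4 h, 5587, 5513 and 6399 for the strain differences and 3342 in glucose medium. A replicate block within each strain gave 7289, 7269, 7444, 7509, 2856, 1779, 5813, 5701 and 6503 for the first 9 of these. Neither block moved a count by 1.5 times, and apart from the R21 difference of gprH between 8 h and 4 h (−0.75, adjusted p = 0.0591, and 0.0308 and 0.00146 with the blocks) neither changed any other call of a named gene. For the strain differences these blocks only take variance between replicates out of the error. They therefore cannot test whether paired arrays may be counted as independent there.

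Median centring moved the median of all genes from 0.04 to 0.06 in the 4 responses to 0.38 and 0.40 in R21 and 0.29 and 0.30 in ∆gprH, and the share of higher calls from 52.3%, 51.8%, 52.9% and 52.4% to 66.6%, 66.2%, 63.9% and 63.7%. It moved that share from 52.6%, 55.1% and 52.8% to 42.6%, 44.2% and 42.7% in the strain differences, and Agilent's log ratios moved it to 44.1%, 45.2% and 44.1%. In glucose medium the share was 42.7%, 56.9% with median scaling and 53.1% with quantile-normalized processed signals. Under the 4 scalings of the log2 ratios and the 3 of the glucose channels, 0 of the 76 called lists changed the sign of the median. The 215 values printed for named genes kept their direction under every alternative run for them: 3221 alternative values stayed on the same side of the threshold, 13 newly passed it and 3 no longer did. Most of these genes were named for large changes that passed in these same data. That choice made such stability likely, and it does not extend to other genes. Between 8 h and 4 h in ∆gprH rodA no longer passed with Agilent's log ratios, the deposited value table or the background model on all spots. Passing under some alternatives only were that gprH difference in R21, which also passed with both of these sets of ratios, median centring, equal spread, slide as a random block and the compared groups alone, and the ivoA response of ∆gprH at 8 h, at 0.22 to 0.87 where it passed. These ivoA values are not measured sizes, as its glucose channel there was not well above background.

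Signal over background limits what the arrays show for weak genes: in the glucose channel 54.5% to 74.0% of genes were well above background, and a response of a gene below that level is only a bound.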

Other observations

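Every value in this part was chosen for description only after the results were seen, from lists fixed or named genes chosen as stated above.

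The disulphide isomerase gene pdiA of the endoplasmic reticulum was at 1.34 ± 0.21 (n = 3) and 2.52 ± 0.13 in R21 at 4 h and 8 h, and at 2.56 ± 0.23 and 1.34 ± 0.08 in ∆gprH. Between 8 h and 4 h it was higher by 1.18 (adjusted p = 7.7e-05) in R21 and lower by −1.22 (adjusted p = 0.000174) in ∆gprH, and its strain difference was 1.22 (adjusted p = 1.09e-05) at 4 h and −1.18 (adjusted p = 1.37e-05) at 8 h. clxA, calnexin, had a strain difference of 1.36 (adjusted p = 0.000154) at 4 h. Among 11 chaperone genes the mitochondrial grpE fell in every group, by −1.36 ± 0.08 and −1.42 ± 0.13 in R21 and −2.26 ± 0.05 and −2.24 ± 0.08 in ∆gprH. As a list, chaperones were not called in any of the 4 responses (adjusted p = 0.99, 0.535, 0.851 and 0.682), and their median and mean differed in sign in R21 at 4 h and in ∆gprH at 8 h.

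Single genes of sugar transport and of the wall changed, while their lists were not called. The transporter gene hxtA rose by 3.73 ± 0.29 and 3.97 ± 0.23 in R21 and by 4.64 ± 0.25 and 4.35 ± 0.26 in ∆gprH, and the low-affinity glucose transporter mstE fell, at −3.75 ± 0.61, −3.86 ± 0.01, −2.75 ± 0.12 and −2.98 ± 0.37 in the same order. The high-affinity glucose transporter mstA was 3.59 (adjusted p = 2.54e-08) higher in the ∆gprH response at 4 h, with the R21 glucose channel above background on 1 of 3 arrays. The xylanase gene xlnA was higher by 3.54 (adjusted p = 3.15e-09) at 4 h and 4.15 (adjusted p = 7.48e-10) at 8 h, with glucose channels above background on 1 of 3 arrays in ∆gprH at 4 h and in R21 at 8 h, and agdA by 2.90 (adjusted p = 1.28e-09) and 2.57 (adjusted p = 2.71e-09). The alpha-glucan synthase ags1 fell at −3.24 ± 0.37 and −2.83 ± 0.04 at 4 h, while gel1, a glucan-modifying enzyme of the wall, differed between strains by 2.29 (adjusted p = 1.34e-07) and 1.97 (adjusted p = 4.16e-07). The wall synthesis list was not called in any response (adjusted p = 0.914, 0.947, 0.858 and 0.738, with median and mean of opposite sign in R21 at both times and in ∆gprH at 4 h). Hexose transporters were not called either (adjusted p = 0.744, 0.751, 0.473 and 0.77).

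The zinc transporter gene zrfA was low after starvation in R21, at −3.35 ± 0.38 and −3.36 ± 0.16, and in glucose-grown RNA it was lower in ∆gprH by −3.18 (adjusted p = 3.29e-11), with its glucose channel above background on 2 of 3 ∆gprH 4 h arrays. The secreted protease gene prtA was at 3.96 ± 0.09 in R21 and 4.19 ± 0.39 in ∆gprH at 8 h. chiB had a strain difference of −2.22 (adjusted p = 0.000292) at 4 h, opposite to the median of 1.69 over the 5 autolysis genes, its list.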
